A study of Drosophila melanogaster with 3 samples.

How the data were processed

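The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq) of Pdp1, a basic leucine zipper transcription factor of the PAR family, in whole embryos of Drosophila melanogaster. Per the labels, the flies carried an intronic eGFP exon that turns the endogenous Pdp1 gene into a Pdp1-eGFP fusion, the precipitating antibody recognised GFP, the embryos were 0 to 24 h old and of mixed sex, and chromatin was sonicated to fragments of 200 to 800 bp. The 3 samples are biological replicates of a single group, so no comparison between groups was possible. Lists from untagged or mock-precipitated embryos were not analysed here.

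The authors deposited peak lists in the narrowPeak format in coordinates of 2 genome builds, dm3 and dm6. Per the listings that accompany the deposited lists, each replicate has a relaxed list called against a control, a further relaxed list was called on the 3 replicates pooled, and a thresholded list holds the peaks kept by the irreproducible discovery rate (IDR) procedure. The aligner, the peak caller and their versions are not given in the sources used here. Each peak carries a signal value from the authors' peak caller, which is not scaled between lists. It was used to rank, filter or describe peaks within a list. For named peaks its mean ± SD over the 3 replicate lists is also given, as a description only. That SD can include differences in scale between the lists, whose dm6 medians were 21.3, 15.1 and 15.2 in replicates 1, 2 and 3. The deposited −log10 of the q-value was read to describe the thresholded list and entered no test. Read numbers were not analysed here, so sequencing depth is unknown, and each replicate list holds 30000 peaks. All 4622 thresholded dm6 peaks were in the pooled relaxed list, and they were exactly the peaks of that list with a signal of at least 102. They shared 1 deposited −log10 q, 3.98, so this value does not order them. Of the thresholded peaks, 69.4% had the same width, 410 bp.

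Summits were taken as the peak start plus the deposited offset. Annotation used only dm6 lists, the Release 6 genome sequence and Ensembl gene models of release 115, restricted to 6 chromosome arms (2L, 2R, 3L, 3R, 4 and X). The highest peak end on each arm lay inside the reference sequence. The dm3 lists were counted and not converted. Each summit was put in 1 class, in the order promoter (within 500 bp of a transcription start site, TSS, of a protein-coding gene), 5' UTR, 3' UTR, coding sequence, intron and intergenic. Class shares were compared with 1000 random placements of the summits on the same arm by a two-sided permutation test. Support by a replicate was a summit within 100 bp among its top 4622 peaks, with a one-sided test against 1000 placements.

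The PAR bZIP site TTAYGTAA (Y is C or T) was searched on both strands within 50 bp of the summit and in windows of equal width 500 bp away, with an exact two-sided McNemar test against the right-hand window. All 8-mers seen in at least 20 windows were tested in the same way. Gene lists, 22 in number, were written before the data were examined. Their genes were matched by symbol or, for 9 entries, by a RefSeq synonym, and 9 entries had no match, 1 of them because its only synonym match was an unrelated gene, an exclusion made after seeing the data. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test on genes with a summit within 500 bp of a TSS, and odds ratios include a pseudocount of 0.5. A further test drew 10000 random lists matched on the number of distinct TSSs per gene. The p-values of classes, 8-mers and lists were adjusted by the Benjamini-Hochberg method within each family. Intervals of proportions are 95% Wilson intervals. Those of stratified odds ratios are 95% normal intervals on the log scale of the Mantel-Haenszel odds ratio over 10 equal parts of pooled signal, with the Robins-Breslow-Greenland standard error. That of the excess within 200 bp is a normal interval of the difference per peak from the mean of both flanks, the wider limit with flanks at 500 or 1000 bp being given. All cover counting error only. Values as mean ± SD are over the top 4622 peaks of the 3 replicate lists.

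Named items followed a rule fixed before the data were examined. It took the nearest genes of the 20 highest-signal thresholded peaks supported in all 3 replicates, every clock gene, up to 4 members of each other list with the highest-signal promoter peak, and the 5 8-mers with the largest ratio of summit to flank windows among those past the threshold of 0.05. One item that the rule takes is not reported here. Items outside it are said to have been chosen after their values were seen. Replicate signals of a named peak are those of the nearest summit within 100 bp in each whole replicate list.

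Alternatives fixed beforehand were other match distances and TSS windows, stricter peak sets, other motif forms and windows, a k-mer length of 6, flanks at 1000 bp, whole gene bodies with 2000 bp upstream, lists matched on TSS number, and leaving out each replicate in turn. Leaving out a replicate meant keeping the thresholded peaks supported by the other replicates, which also shortens the list. The statistics were tested on simulated peak lists. For the motif, 200 of 200 planted sites were recovered and 3 of 50 random lists passed the threshold of 0.05. For gene lists, 20 of 20 seeded genes were recovered and 1 of 50 random lists passed. No 8-mer passed in 3 random lists. Random summits were placed evenly along each arm, without the promoter share or the G and C difference of the real ones. Planted summits lay exactly on a motif or, for the seeded genes, on a TSS. The simulations therefore do not cover calls that arise from base composition or promoter location. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.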

Results

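Binding of the PAR-domain factor Pdp1, tagged with eGFP at its own locus, was mapped by ChIP-seq with an anti-GFP antibody in 3 biological replicates of whole embryos collected over 0 to 24 h. Pdp1 is known as a regulator of the circadian clock gene Clk in adult flies and of muscle genes and growth in embryos and larvae. The pooled call held 27719 relaxed dm6 peaks, of which 4622 passed the IDR threshold, and these covered 1.22% of the 134 Mb on the chromosome arms. In dm3 coordinates the corresponding lists held 24831 and 4488 peaks. Each replicate list held 30000 peaks in either build.

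The labels imply a first question, whether the replicates bound the same places. Of the top 4622 peaks of replicate 1, 64.0% had a summit within 100 bp among those of replicate 2 and 72.3% among those of replicate 3, and for replicates 2 and 3 the share was 62.9%. Of the 4622 thresholded summits, 2550 (55.2%) lay within 100 bp of a summit among the top 4622 peaks of all 3 replicates, against a mean of 0.316% for random placements (one-sided permutation p = 0.001, the smallest that 1000 placements can give). A further 1417 were supported in 2 replicates, 601 in 1 and 54 in none. The thresholded peaks came from the pooled reads of these replicates, so this support is in part fixed by their selection. They were exactly the pooled peaks with a signal of at least 102, so agreement between replicates did not select them peak by peak. Single replicates supported 79.9% ± 3.91 (SD, n = 3), with 83.3% in replicate 1, 75.6% in replicate 2 and 80.9% in replicate 3. In the whole lists of 30000 peaks, replicate 2 held 84.4% of the thresholded summits, against 97.3% in replicate 1 and 96.7% in replicate 3. Spearman's rho of the signal across shared peaks was 0.714 for replicates 1 and 2 (3799 peaks), 0.779 for 1 and 3 (4362 peaks) and 0.702 for 2 and 3 (3776 peaks). These correlations run across peaks, which are not independent replicates.

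**Figure D1:**
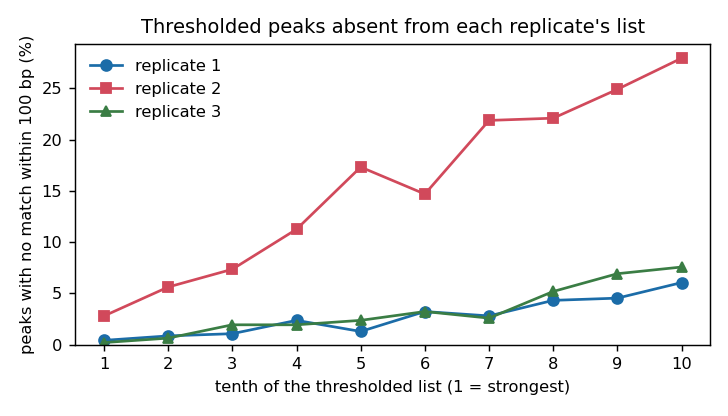
Share of thresholded peaks with no summit within 100 bp in the whole list of each replicate (y axis, %), by pooled signal in 10 equal parts of the thresholded list (x axis, 1 = strongest), with 1 line per replicate. Replicate 2 lacked 2.81% of the strongest part and 27.9% of the weakest, and replicates 1 and 3 lacked 6.06% and 7.58% of the weakest.

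The strongest peaks lay at promoters and introns of genes with varied roles. The peak of highest pooled signal was at X:2703678-2704107 (dm6), 41 bp upstream of a TSS of Ugalt (FBgn0024994), a UDP-galactose transporter. Over the replicate lists, which are not scaled to each other, this peak had a signal of 1150 ± 205 (SD, n = 3). It was followed by a promoter peak of CG14100 (FBgn0036889) at 3L:19590404-19590832, with 1143 ± 278 (n = 3), and by a peak at 2L:480859-481340 in an intron of ush, whose nearest TSS was that of cbt (FBgn0043364), with 1119 ± 142 (n = 3). Next came promoter peaks of ph-p, a Polycomb group gene, at X:2137133-2137584 (862 ± 134, n = 3) and of Chro, which encodes the chromatin protein Chromator, at 3L:22878689-22879123 (816 ± 136, n = 3). The other 15 of the 20 highest peaks supported in all replicates were nearest to CG11050, Art3, Lk6, PNPase, CG1888, CenG1A, Tcs5, mRpL41, px, CG9663, CG13323, HmgZ, Pal1, CG31145 and CG32772. Of the 20, 13 were at promoters, 6 in introns and 1, 11897 bp from the TSS of CG13323, was intergenic. None of the 20 had TTAYGTAA within 50 bp of its summit, and none had TATCGATA, a site described below. With TTAYGTAA at 1.19% of all thresholded summits, 20 peaks are too few to read anything from its absence.

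Promoters held 2257 of the 4622 summits (48.8%), 4.25 times the 11.5% ± 0.490 (SD) of the random placements. The share was 48.2% ± 4.21 (SD, n = 3) in the replicate lists, so the excess over random placement was larger than the spread between replicates. Coding sequence held only 11 summits (0.238%) against 13.3% at random, and 3' UTRs held 0.779% against 5.19%. Introns held 34.2% against 39.4% and intergenic sequence 15.4% against 29.9%. Each of these 5 shares gave a two-sided permutation p of 0.002 (adjusted p = 0.0024), the smallest that the placements can give, and 5' UTRs, with 0.498% against 0.797%, gave an adjusted permutation p of 0.02. Among the other peaks of the pooled relaxed list, a comparison chosen after seeing the data, 23.7% of summits were at promoters and 34.8% in introns. Against those peaks the promoter excess was smaller than against random placement, and the intron share was nearly alike. Split by signal into 4 equal parts, the strongest thresholded peaks had 57.1% at promoters and the weakest 42.0%. Of the promoter summits, 40.7% lay within 500 bp of TSSs of 2 or more genes, so a promoter peak often cannot be assigned to a single gene. In all, 2883 of 13945 protein-coding genes (20.7%) had a promoter peak, with 19.9% ± 1.54 (SD, n = 3) in the replicate lists.

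**Figure D2:**
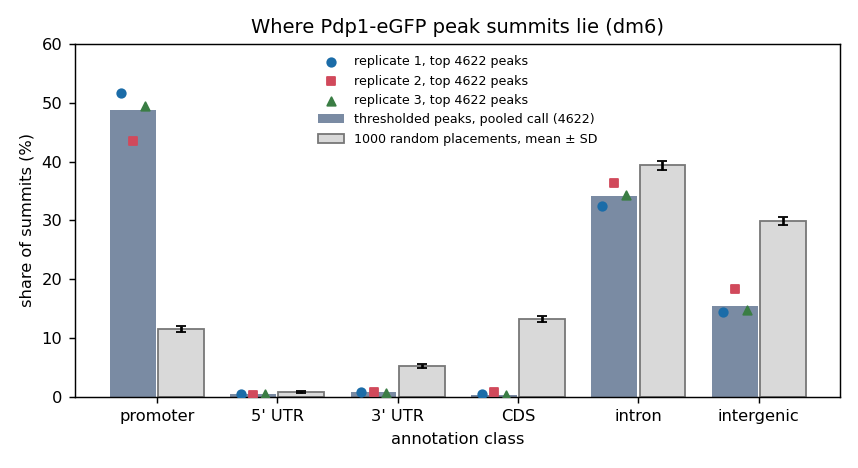
Share of summits (y axis, %) in each annotation class (x axis) for the pooled thresholded list (filled bars), the top peaks of each replicate list (points) and 1000 random placements (open bars, mean ± SD). Promoters took 48.8% of summits against 11.5% at random, and coding sequence 0.238% against 13.3%.

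The gene lists asked which processes had promoters with peaks. Genes of cytosolic ribosomal proteins stood out, with peaks at 59 of 85 (69.4%; odds ratio 8.77, adjusted p = 8.5e-21 by Fisher's exact test), and 64.3% ± 14.0 (SD, n = 3) in the replicate lists. By replicate, the share was 70.6%, 48.2% and 74.1% in replicates 1, 2 and 3. The odds ratio was 3.46 without replicate 1, 3.10 without replicate 3 and 8.82 without replicate 2. Leaving out replicate 1 or 3 kept only peaks supported in replicate 2. In peaks supported by all replicates the odds ratio was 3.24. Among genes with a relaxed promoter peak, a background chosen after seeing the data, it was 4.14. The strongest of these peaks were at RpL32 (3R:30046099-30046536), RpL34b, RpS27 and RpL7. Promoter peaks were also more frequent at circadian clock genes, with 10 of 20 (odds ratio 3.85, adjusted Fisher's exact p = 0.0183), and at genes of bZIP transcription factors, with 9 of 19 (odds ratio 3.48, adjusted p = 0.0365). The latter were led by Atf3, REPTOR, Irbp18 and Xbp1, and the Atf3 peak had a signal of 471 ± 94.0 (SD, n = 3). Fewer promoters than among other genes had a peak for odorant and gustatory receptors (0 of 119, adjusted Fisher's exact p = 1.56e-11), Cpr cuticle proteins (0 of 70, adjusted p = 9.69e-07) and early patterning genes (1 of 30, bcd, adjusted p = 0.0462). Against random lists matched on the number of TSSs, the ribosomal protein call held (adjusted permutation p = 0.00147), as did those of the receptors and Cpr genes at the same p, while the calls for clock genes (adjusted p = 0.157), bZIP genes (adjusted p = 0.2) and patterning genes (adjusted p = 0.0528) were lost. The clock call was also lost without replicate 1 (adjusted Fisher's exact p = 0.371) or replicate 3 (adjusted p = 0.179), in the upper 2311 peaks by signal (adjusted p = 0.13), in peaks supported by all replicates (adjusted p = 0.316) and within 200 bp (adjusted p = 0.608). The bZIP call was also lost without replicate 2 (adjusted Fisher's exact p = 0.0675) and within 200 bp (adjusted p = 0.608). The patterning call was kept under no other planned setting, with an adjusted exact or permutation p from 0.0528 to 0.371.

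The clock genes with a promoter peak included sgg, with the peak at X:2646189-2646597 and a signal of 193 ± 18.8 (SD, n = 3), dco, with 2 promoter summits, CkIIbeta, mts, tws, slmb, ctrip and Fbxl4. The peak credited to Fbxl4 lay inside the neighbouring gene Dus2 and that of mts inside Rack1. In other lists, the peaks credited to Irbp18, mbc, elav, moody, imd and Rpn5 also lay inside a neighbouring gene. The remaining clock genes with a promoter peak were vri and cry. The gene vri, a bZIP repressor of Clk, had a promoter peak at 2L:5299236-5299645 with 79.2 ± 12.2 (SD, n = 3), and cry, the photoreceptor gene, a weak peak at 3R:19211660-19212069 with 34.9 ± 10.6 (SD, n = 3). Pdp1 itself had no promoter summit in the thresholded list, but 1 in the top list of each replicate, and 4 thresholded summits in its gene body, the strongest in an intron at 3L:7850918-7851327 with 83.9 ± 58.2 (SD, n = 3), and cwo had 1 intronic summit. No thresholded summit lay in the gene or within 2000 bp upstream of Clk, cyc, per, tim, jet, CkIIalpha, Pdf or Pdfr.

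Muscle genes, with which Pdp1 has been linked, passed no threshold. Contractile muscle genes had promoter peaks at 3 of 27 (Msp300, sls and Tm1; adjusted Fisher's exact p = 0.439), and genes of muscle specification and fusion at 5 of 25, among them mbc, org-1, rols and tin (adjusted p = 1). Random lists matched to the contractile muscle genes on TSS number had 8.75 genes with a peak on average. The shortfall from that number narrowly missed the threshold (adjusted permutation p = 0.055). Metabolic lists had higher shares that missed the threshold, 8 of 21 for fat body and lipid storage, led by Lpin, Mtp, SREBP and Hnf4, and 8 of 21 for insulin and TOR signalling, among them Pi3K21B, InR and step (adjusted exact p = 0.125 for both). The fat body list passed without replicate 2 (adjusted exact p = 0.042), and the insulin and TOR list passed within 1000 bp (adjusted exact p = 0.0494) and over gene bodies (adjusted exact p = 0.0442). Genes of trachea had 6 of 15 (pck, crb, trh and bs the highest; adjusted exact p = 0.159), proteasome subunits 15 of 48 (Rpn5, Rpn3, Rpn6 and Rpn11 the highest; adjusted p = 0.127) and maternal germline genes 4 of 19 (bgcn, stau, tud and vas; adjusted p = 1). Ecdysone and juvenile hormone genes had 4 of 25 (Eip75B, usp, gce and EcR; adjusted exact p = 0.932), glial genes 3 of 17 (moody, ana and wrapper; adjusted p = 1), and neuronal genes (elav, nerfin-1 and insc) and hemocyte and immune genes (imd, cact and PPO3) 3 of 27 each (adjusted p = 0.439 for both). Epidermal cuticle genes had 2 of 29 (rtv and shn; adjusted exact p = 0.125), midgut genes 1 of 22 (fkh; adjusted p = 0.125) and Hox genes 1 of 11 (Antp; adjusted p = 0.585). Testis genes had 0 of 19 (adjusted exact p = 0.0645) and chorion genes 0 of 18 (adjusted p = 0.0966). Both of these lists fell below other genes within 1000 bp (adjusted exact p = 0.0434 for each), and chorion genes did so over gene bodies (adjusted exact p = 0.0167). These lists are small, and a missed threshold does not show that their share equals that of other genes.

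**Figure D3:**
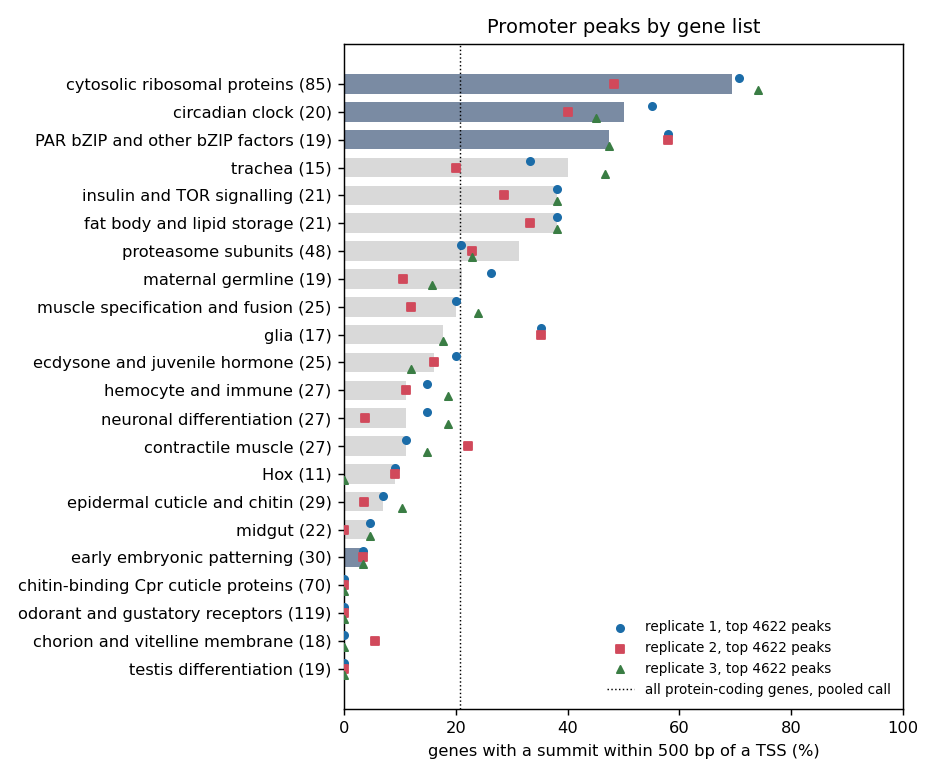
Share of each list's genes with a summit within 500 bp of a TSS (x axis, %), by list (y axis, number of genes in parentheses), for the pooled call (bars, dark where the adjusted p is under 0.05) and the top peaks of each replicate (points). The dotted line marks all protein-coding genes (20.7%), and ribosomal protein genes reached 69.4%.

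The PAR bZIP site was rare at the summits. TTAYGTAA occurred within 50 bp of 55 of 4622 summits (1.19%, 95% interval 0.915 to 1.55%) and in 0.638% of the flanking windows on average, 32 on the right and 27 on the left (exact McNemar p = 0.0178 against the right). The replicate lists had 1.13% ± 0.0125 (SD, n = 3). With the peaks in 4 equal parts by signal, the strongest part had the site at 14 of 1155 summits and the weakest at 11 of 1155 (Fisher's exact p = 0.688). Of the other peaks in the pooled relaxed list, 0.619% had the site (Fisher's exact p = 7.69e-05), a comparison chosen after seeing the data and not adjusted for base composition, with 45.0% G and C at those summits against 35.4% at the thresholded ones. The excess over the flanks also passed within 100 bp (exact p = 0.00335), for the looser form TTAYRTAA (exact p = 0.000995) and without any 1 replicate (exact p from 0.00444 to 0.044). It missed the threshold within 25 bp, where 29 summits and 16 flanks had the site (exact p = 0.0725), for the longer form RTTAYGTAAY (exact p = 0.815), and, in a comparison chosen after seeing the data, in the top list of each replicate (exact p from 0.0503 to 0.137).

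Other sequences had larger ratios of summit windows to flanks 500 bp away than the PAR site. Of 15728 8-mers tested, 1235 were more frequent and 768 less frequent at the summits than in the flanks, and with a length of 6 the balance turned to 500 and 879. The 5 largest ratios belonged to AACCTTAA (28 summits against 1 flank), ACTTAGAA (23 against 1), AGCCCTGG (33 against 2), AGGGCTGC (46 against 3) and ATCGATAG (109 against 8), and ATCGATAG also had the smallest p (adjusted p = 1.39e-19 by the exact McNemar test). TATCGATA, the palindromic DNA replication-related element (DRE) bound by DREF and chosen here after its values were seen, was at 103 summits (2.23%) and 12 flanks (0.26%), with 1.95% ± 0.565 (SD, n = 3) in the replicate lists. Closer to the summit it was nearly flat, with a mean of 0.492% per 20 bp bin within 40 bp and 0.426% at 80 to 140 bp (ratio 1.16), where TTAYGTAA had 0.281% and 0.188% (ratio 1.5), a comparison chosen after seeing the data. The PAR site form TTATGTAA had 46 summits against 27 flanks (adjusted exact p = 0.152). Repeats of CA were less frequent, with CACACACA at 47 summits and 183 flanks. Summit windows held 35.4% G and C, against 43.7% in the flanks, and the 8-mer tests were not adjusted for that difference. Of the 136 tested 8-mers made only of A and T, 112 were among the more frequent. The 1023 other 8-mers with as many G and C as TTATGTAA had a median ratio of 1.86, against 1.69 for TTATGTAA. Without replicate 2, 762 8-mers were more frequent.

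**Figure D4:**
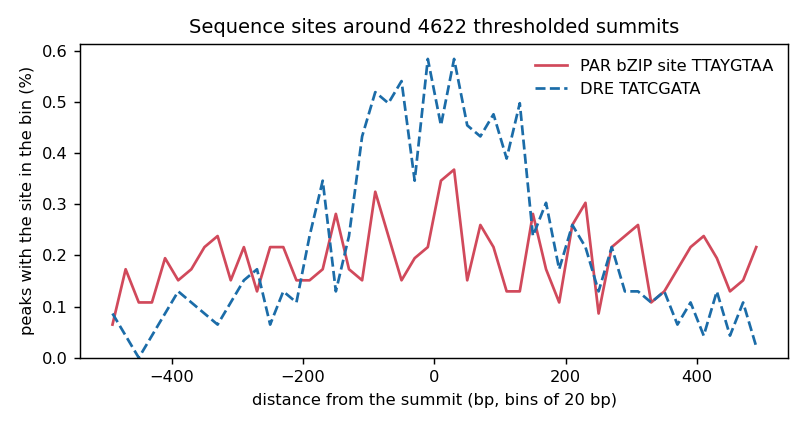
Share of the thresholded peaks (y axis, %) with TTAYGTAA (solid line) or TATCGATA (dashed line) in bins of 20 bp by distance from the summit (x axis, bp). TATCGATA was within 50 bp of 2.23% of summits and TTAYGTAA of 1.19%.

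Peaks were spread over all arms, with 38.3 thresholded peaks per Mb on X, 36.5 on 2L, 34.8 on 3R, 32.6 on 2R and 32.3 on 3L. The small chromosome 4 had 16 peaks, or 11.9 per Mb. The density on X was 1.13 times that of the major autosome arms (exact binomial p = 0.00157). This excess was no larger than the spread of the ratio between replicates, 1.13 ± 0.130 (SD, n = 3), and in the whole pooled relaxed list the ratio turned to 0.913 (exact binomial p = 1.5e-08). The ratio was 1.28 without replicate 1 (exact binomial p = 1.18e-07), 1.11 without replicate 2 (exact binomial p = 0.0231), 1.29 without replicate 3 (exact binomial p = 3.83e-08) and 1.27 in peaks supported by all replicates (exact binomial p = 1.4e-06).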

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

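The counts of scaffold peaks were examined only after the lists had been read, and both tests below on the peaks that replicate 2 lacks were written down before their results were seen. The dm3 relaxed lists, which the comparisons above do not use, held peaks on heterochromatic and unplaced scaffolds, above a count of 0 in each replicate. There were 31 in replicate 1, 676 in replicate 2 and 26 in replicate 3. In replicate 2 the largest numbers were on 3LHet (203), 2RHet (193) and 3RHet (189). Of the 676 in replicate 2, only 20 were among the 4622 peaks of highest signal in its dm3 list, against 0 in replicates 1 and 3.

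Replicate 2 stood apart in other values too: 720 thresholded peaks had no match in its whole list, against 125 and 151 in replicates 1 and 3, and chromosome 4 held 27 of its relaxed peaks, against 197 and 289. Loss of GC-rich fragments stays open: at equal pooled signal its missing peaks differed from the found ones by 0.194 percentage points of GC (permutation p = 0.353), under the bound of 1 set beforehand, but that bound took no account of the other replicates, whose differences were -1.96 and -1.66. This reading replaced that of the bound after the result was seen. Weaker enrichment or lower depth stays open too. At equal signal its missing peaks were more often promoter peaks (odds ratio 1.61, 95% interval 1.37 to 1.90), which had been set down as evidence against that explanation, but the odds ratios of 2.01 in replicate 1 and 1.72 in replicate 3 have overlapping intervals, so that criterion was wrong and the test says nothing particular to replicate 2. Read depths were not analysed here, all samples belong to a single group, and no biological explanation was tested.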

How the results depend on the processing

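Comparisons with other relaxed peaks or with a relaxed background, and those of single replicate lists, were chosen after seeing the data. Replicate support and the promoter share kept their direction and side of the threshold under all alternatives run, from 41.0 to 85.1% and from 36.0 to 58.2%. Where values changed, the cause was not tested. Rank correlations rose to 0.756 for replicates 1 and 2 and 0.749 for 2 and 3 with a match within 50 bp. The excess of the PAR site missed the threshold within 25 bp (0.627%), for RTTAYGTAAY (0.216%) and in the top lists of replicates 1, 2 and 3 (1.13%, 1.13% and 1.15%). Its difference between the strongest and weakest of 4 equal parts, 0.26 percentage points and never past the threshold, turned to -0.693 in the upper 2311 peaks, -1.10 in peaks supported by all replicates and -0.433 with 10 parts, and ranged from -0.958 to 0.123 without 1 replicate. More frequent 8-mers numbered 673 in the upper 2311 peaks (162 less frequent), 800 in supported peaks (216), 762 to 966 without 1 replicate (303 to 315) and 862 with flanks at 1000 bp (608). With a length of 6 the balance was reversed, with 500 more and 879 less frequent. The X to autosome ratio turned to 0.913 in the whole relaxed list. Lists with more promoter peaks fell from 3 to 1 within 200 bp, to 1 against lists matched on TSS number and to 1 with the relaxed background. For single lists, 21 calls were lost and 7 gained over all settings, and for the 93 named genes the promoter peak was lost in 136 cases, gained in 9 and unaltered in 599.

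In 10 lists that passed no threshold in the settings concerned, the odds ratio crossed 1 in 35 cases (smallest adjusted exact or permutation p = 0.155). In the upper 2311 peaks it became 1.10 for ecdysone, 0.574 for germline and 0.895 for proteasome genes, and in supported peaks 1.03 for contractile muscle and for hemocyte, 1.12 for ecdysone, 0.584 for germline and 0.911 for proteasome genes. Within 200 bp it was 0.610 for muscle specification and 0.735 for fat body, and within 1000 bp 0.858 for muscle specification, 2.29 for glia and 1.17 for hemocyte genes. Over gene bodies it was 0.954 for muscle specification, 2.18 for ecdysone, 1.41 for neuronal, 2.11 for glial, 1.64 for hemocyte and 1.99 for Hox genes, and with the relaxed background there 0.606 for muscle specification, 1.87 for ecdysone, 1.27 for glial, 1.55 for hemocyte and 1.20 for Hox genes. Matched on TSS number, the ratio to the expected count was 0.816 for muscle specification and 0.968 for germline, and with relaxed promoters as background the odds ratio for germline was 0.883. Without 1 replicate it ranged from 0.964 to 1.48 for muscle specification, 0.857 to 1.02 for ecdysone, 0.50 to 1.5 for glia, 0.446 to 0.886 for germline and 0.783 to 1.16 for proteasome genes. Depth limits all of this in an unknown way, since the lists carry no read numbers.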

Other observations

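Items in this part were chosen after their values were seen. Several genes carried many separate summits within the gene or 2000 bp upstream: 16 in CG1677, 14 in ush, a GATA cofactor gene, 13 in kirre, a myoblast attraction gene, and 12 each in Raf, sbb and shn. CHES-1-like, with 11 summits in 27.0 kb, was the most densely covered of the 8 genes with the highest numbers, at 37.9 per 100 kb. In kirre the summits lay over 394 kb, at 3.28 per 100 kb, no denser than on the X arm as a whole (38.3 per Mb). The rest of the 8 had 12.6 or more per 100 kb. Summits inside such long genes can belong to nested genes.

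TATCGATA was within 50 bp of 95 of 2257 promoter summits (4.21%) and 8 of 2365 others (0.338%; odds ratio 12.9, Fisher's exact p = 1.87e-21). ATTTTAAA, made only of A and T, was frequent in both classes, at 122 promoter summits against 27 of their flanks and at 124 other summits against 50. These counts were not adjusted for base composition. CAACACTG was at 76 promoter summits against 8 of their flanks. Among other summits the smallest p belonged to CACTGAGA, at 51 summits against 3 flanks (adjusted exact p = 1.7e-08), and AGATGGCG was at 44 against 5. The PAR site showed no detectable difference, with 1.15% of promoter summits and 1.23% of others (Fisher's exact p = 0.892). The strongest peak with a PAR site, of pooled signal 1390, was at X:5918735-5919095 in an intron, 1767 bp from a TSS of CG3726. It was followed by promoter peaks of Brf (711), org-1 (517) and Ctl2 (392). These values are pooled signals, and on that scale the highest peak, at Ugalt, had 3424. They cannot be set against the replicate means given above for named peaks.

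The rarity of the PAR site at Pdp1-eGFP summits was weighed against 3 explanations, of which only that of base composition had its test set down before the result. Dilution by weak peaks is argued against, because the upper 95% limit of the share is 2.02% among the strongest 1155 peaks. Summits misplaced by up to 200 bp are argued against as the cause, since within that distance 4.15% of peaks had the site, at most 1.87 percentage points above the flanks by the upper 95% limit, in a test that replaced earlier ones based on TATCGATA, which had been picked for its ratio. The small excess over the flanks may come from the AT-rich summits, since the ratio of TTATGTAA, 1.69, lies at percentile 38.2 among 1023 8-mers with as many G and C. TATCGATA lies at percentile 99.9 among the 3461 8-mers with its own number of G and C. It was picked for its ratio, so its percentile is no independent contrast. Left open is that the fusion protein was recruited to promoters without its site, or that the peaks reflect promoters open to any precipitation, which mock lists, not analysed here, would be needed to test. As worded, neither covers the 2365 summits outside promoters, where the site was also rare (1.23%, against 1.15% at promoters).

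For the peaks at ribosomal protein genes, the lists matched on TSS number were fixed beforehand but their reading as a test of this pattern was set down after the result, and the test of neighbouring genes was set down before it. More TSSs per gene is argued against as the whole cause, since lists matched on that number gave an adjusted permutation p of 0.00147. For 54 of the 59 genes with a peak (91.5%, 95% interval 81.6 to 96.3%) their own TSS was nearest to a summit, ties included. This met the bound set beforehand against peaks of neighbouring promoters. However, only summits within 500 bp of the gene's own TSS counted, and any such summit sufficed, which favoured this outcome. No share for other genes was computed, so the test does not decide this explanation. High transcription of these genes in embryos, with non-specific recovery of their open promoters, may also contribute and was not tested. No biological explanation was tested.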
